A study of Mus musculus with 12 samples.

How the data were processed

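Total RNA from spheroids of primary mouse hepatocytes was labelled with biotin and read on 12 expression arrays. The spheroids came from 4 preparations, 2 male and 2 female, each a frozen pool of hepatocytes from 3 C57BL/6 animals, and each preparation was sampled at culture days 1, 7 and 14. Groups were taken from the sample labels, which give sex, donor number and day, so that 6 groups of sex and day held 2 arrays each. The values as deposited are on the log2 scale, with 1 value per probe set and array. The submitters' processing notes name RMA (robust multi-array averaging, which corrects background, normalizes between arrays and summarizes probes), Transcriptome Analysis Console 4.0 and Partek 7.0, without saying what each did or in which order. The array build, the annotation release and any filter are not given in the sources used here. No scanner files were used here, so background and normalization were taken as deposited, and 0 columns of per-sample values were left unused.

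The table held 13081 probe sets. Each reached at least 4.79 on at least 1 array, so a filter on low values had been applied before deposit, and 2214 of them lay under that level on another array. The highest value was 12.84 and 55 probe sets lay above 12 on every array, a range in which RMA values are compressed and a rise or fall is understated. A group mean under 4.79 is taken here as near the background, where a fold change may also be understated. No background level was measured. Genes with such a mean entered through at least 1 array at or above 4.79, so the filter selected them on a higher value. Gene symbols came from the platform annotation: 11889 probe sets had 1 symbol, 1192 had none and 0 had several. All 11889 symbols were matched through their gene number to a list of mouse genes (GRCm38.p6), used for names only, and 0 needed an update. For the 19 symbols on several probe sets the one with the highest mean over the 12 arrays was kept, which left 11861 genes. No coordinates are printed, since the build behind the probe sets is not known. Probe sequences were not analysed here, so members of gene families with near-identical copies (the Mup, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a and Sult2a genes) are reported as uncertain: a probe set of one may read another.

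Tests were run in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Comparisons between days, the sexes within a day and the sex difference in the change over days came from 1 model over all 12 arrays with a mean for each of the 6 groups (lmFit, contrasts.fit and eBayes without trend and not robust). A day comparison is the change within each sex averaged over the sexes, and a sex difference is male minus female. For sex over all days the 3 arrays of a preparation were averaged first, leaving 2 male against 2 female values per gene. All tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 11861 genes. Each ± on a change is the standard error of the model, and each ± on a level is the SD between preparations. The preparations are pools of separate animals, so p-values reflect the spread between pools, not between single mice. The number of arrays limits the precision: the median standard error was 0.0946 for a day comparison, 0.134 for the sexes within a day, 0.076 for sex over all days and 0.189 for the sex difference in a change.

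Before the data were examined, the comparisons, the alternatives, the genes to name and 38 lists of genes were fixed from general knowledge of liver biology. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists with at least 3 measured members. Alternatives were camera with a correlation estimated from the residuals, and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The count of members that passed is given over all genes and adjusted over the list alone. Not tested were lymphocyte markers (0 of 20 measured), erythroid and neutrophil markers (1 of 14) and mesothelial markers (2 of 8). For each day comparison the named genes were the 8 largest rises and 8 largest falls among those that passed and changed with the same sign in all 4 preparations, leaving out predicted and clone-named genes. To these were added, for each list, up to 3 members with the largest change among those that passed, or the 1 largest where none did, of which the text uses some. Alb, Hnf4a, Cyp1a2, Cyp2e1, Cyp3a11, Slc10a1, Abcb11, Abcc2 and Cps1 were always named, and Cyp7a1 had no probe set here. For sex over all days the 8 largest in each direction with the same sign at all 3 days were named, with the sex-biased and sex chromosome lists. For the sex difference in a change, up to 5 genes per direction that passed were to be named. Genes outside this rule are said to have been chosen after their values were seen.

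The same preparations were sampled at each day, so the donor number within a sex pairs the arrays across days. The correlation over genes of a preparation's deviations from its group means was 0.104, 0.036 and 0.224 for males and 0.078, 0.066 and 0.324 for females (days 1 and 7, 1 and 14, 7 and 14). The fit without the pairing was kept as fixed beforehand. With the preparation as a block, the comparison of days 14 and 7 gave 101 genes in place of 58, and values with the block stand beside the named genes and lists whose call it changed.

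Each step was tested on simulated data with 200 genes changed by 1.41-, 2- or 4-fold. They were drawn from the real gene means and from limma's spreads, which borrow between genes. Day 7 against day 1 recovered 56.7%, 91% and 100% of these, day 14 against day 1 61.2%, 91% and 98.5%, and day 14 against day 7 62.7%, 94% and 100%. Male against female over all days recovered 61.2%, 94% and 100%, the sexes at day 14 35.8%, 83.6% and 93.9%, and the sex difference in the change to day 14 1.49%, 56.7% and 89.4%. Of the genes left unchanged, 4 to 11 were called per comparison, and 0 called genes had the wrong direction. All 5 lists shifted by 0.3 were called at day 14 and 0 of 22 lists without a shifted member. The simulated genes varied independently of each other. This run therefore does not show how often lists are called falsely when their genes vary together. Spreads that borrow between genes differ less between genes than the measured ones. Arrays of 1 preparation were also drawn as independent. The shares recovered may thus be higher than those in the real data.

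Alternatives tried were the preparation as a block or as a random effect, leaving out the 40% dimmest genes, centring each array on its median, a second quantile normalization, eBayes with trend and robust, all probe sets, the mean of a gene's probe sets, a minimum of a 2-fold change, an adjusted p under 0.01, an unadjusted p under 0.05 with a 2-fold change, only the arrays of the days compared, each sex alone, and each preparation left out in turn. Leaving out the single array of male preparation 1 at day 14 was added after the data were seen. Without a preparation fewer arrays set the spread, so a call lost there can come from lower precision with the change itself much the same. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 drew the plots.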

Results

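Expression was measured on 12 arrays of spheroids, compact aggregates that hepatocytes form when they are kept from attaching, and which are used as a longer-lived culture for studies of liver function and toxicity. The 4 preparations, 2 male and 2 female, were each a pool of cells from 3 mice of C57BL/6, an inbred laboratory strain. Every preparation was sampled at days 1, 7 and 14 after its spheroids formed, so that each of the 6 groups of sex and day held 2 arrays. The design asks how the spheroids differ between culture days and between the sexes. Values are the deposited log2 levels, and array medians lay between 7.47 and 7.53. Arrays of the same sex and day correlated across genes at r = 0.984 to 0.99, arrays of the other sex on the same day at 0.966 to 0.983, and arrays of the same preparation on other days at 0.963 to 0.986. Genes are not independent replicates, so these values describe the arrays only. Albumin (Alb), the main plasma protein, stood at 12.73 ± 0.015 at day 1 and 12.74 ± 0.03 at day 14 (SD, n = 4), close to the top of the scale. Hnf4a, a master transcription factor of hepatocytes, stood at 11.37 ± 0.06 and 11.22 ± 0.04.

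**Figure D1:**
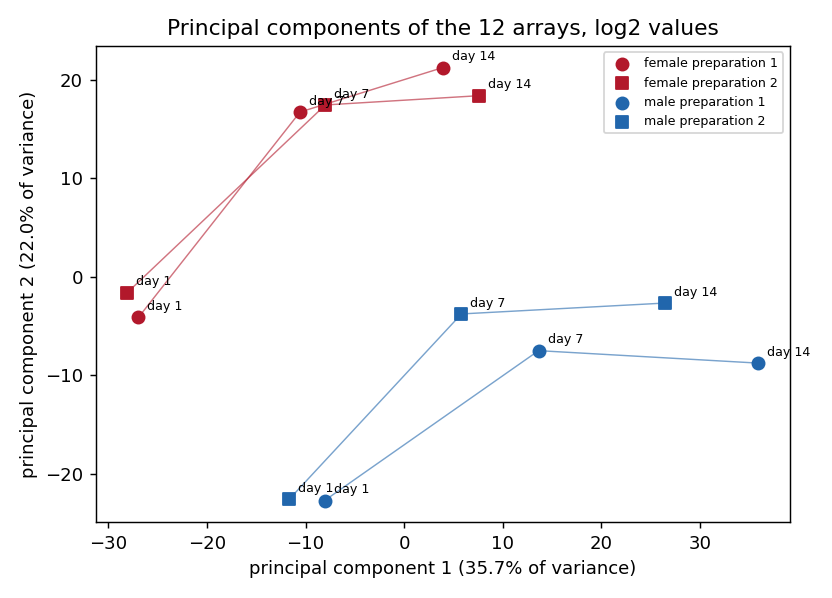
The first (x axis, 35.67% of the variance) and second (y axis, 21.96%) principal components of the log2 levels of the 12 arrays, with colour for sex, a circle for preparation 1 and a square for preparation 2, and a line joining the days of each preparation. Within each preparation the day 1 array lies lowest on the first component (females -28.08 and -26.95, males -11.65 and -8.07), and male preparation 1 at day 14 lies farthest out at 35.9.

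The comparison of day 7 against day 1 asked what changed over the first week. Among the largest rises, the claudin genes Cldn6 and Cldn7, which encode membrane proteins of cell junctions, rose by 2.74 ± 0.27 and 2.28 ± 0.28 on the log2 scale (SE, 4 preparations per day). Ptgs2, the inducible cyclooxygenase, rose by 2.18 ± 0.18, the membrane protease gene Mep1a by 2.32 ± 0.26 and the keratin gene Krt23 by 1.87 ± 0.23. Prl2c3 (1.99 ± 0.25), Chil3, a chitinase-like gene of macrophages (1.96 ± 0.395), and Dpysl3 (1.90 ± 0.27) completed the 8 largest rises. Among the largest falls were Gvin1, an interferon-inducible GTPase gene (-2.58 ± 0.28), the collagen gene Col3a1 (-2.15 ± 0.43), Lox, which cross-links collagen (-1.73 ± 0.14), and Pcolce2, which aids procollagen processing (-1.76 ± 0.18). The protease inhibitor gene A2m (-2.14 ± 0.18), the hormone gene Cck (-1.75 ± 0.22) and the imprinted genes Mest (-2.09 ± 0.42) and Igf2 (-1.73 ± 0.24) also fell. The Igf2 value averages a larger fall in females and a smaller one in males. Adjusted p for these 16 genes ran from 0.00219 (Ptgs2, A2m and Lox) to 0.031 (Chil3), and each changed the same way in all 4 preparations. Cldn6, Ptgs2, A2m and Lox passed with any 1 preparation left out, and each of the others lost its call in at least 1 such fit (adjusted p from 0.0501 for Cck without male 2 to 0.267 for Chil3 without male 2). Cldn6, Cldn7, Ptgs2, Mep1a, Krt23, Chil3, Gvin1 and Pcolce2 each had a day mean under 4.79, near the background.

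Genes of fatty acid oxidation and targets of PPAR alpha, the receptor that turns on fat burning, stood higher as a list in day 7 against day 1. Of these, 12 of 36 measured members rose and 0 fell, and 25 rose adjusted over the list alone (median 0.32, camera adjusted p = 2.9e-15, adjusted p = 0.1 with an estimated correlation). Fabp1, a fatty acid carrier, rose by 1.47 ± 0.27, the pantetheinase gene Vnn1 by 1.10 ± 0.10 and the thioesterase gene Acot1 by 1.03 ± 0.11. In the urea cycle and amino acid list 5 of 30 rose (7 adjusted over the list alone, adjusted p = 7.32e-06, adjusted p = 0.175 with an estimated correlation), among them Haao of tryptophan breakdown by 0.94 and Hpd of tyrosine breakdown by 0.66. Of 36 conjugating enzymes 7 rose and 1 fell (13 and 2 adjusted over the list alone, adjusted p = 0.000529, adjusted p = 0.388 with an estimated correlation), with Gsta4, a glutathione transferase, at 0.67 and Ugt2b37, a glucuronosyltransferase, at -1.43. Of 30 drug-metabolizing cytochromes P450 4 rose (5 up and 3 down adjusted over the list alone, adjusted p = 0.0367, adjusted p = 0.66 with an estimated correlation), including Cyp2b10 by 0.71 and Cyp2d26 by 0.45. Bile acid synthesis had 2 of 14 higher (5 adjusted over the list alone, adjusted p = 0.000613, adjusted p = 0.276 with an estimated correlation). The respiratory chain list had 0 of 34 members past the test alone and 0 adjusted over the list alone, yet stood higher together (median 0.08, adjusted p = 0.000603, adjusted p = 0.1 with an estimated correlation). For the 0 of 20 genes of cholesterol synthesis (also 0 adjusted over the list alone) and the 3 of 22 of fatty acid synthesis (3 up and 1 down adjusted over the list alone) adjusted p was 0.0367 each, and adjusted p = 0.66 and 0.573 with an estimated correlation. With the preparation as a block the fatty acid synthesis list had an adjusted p of 0.0511. The P450 call was lost without male preparation 1 (adjusted p = 0.0533) or female preparation 1 (0.297), that of fatty acid synthesis without male 2 (0.204) or female 1 (0.56), and that of cholesterol synthesis without male 2 (0.238), female 1 (0.115) or female 2 (0.0853). Fabp1, Haao, Hpd, Cyp2b10 and Cyp2d26 did not pass whichever preparation was left out, though their changes stayed close. Fabp1 ran from 1.334 to 1.608, Haao from 0.8522 to 1.027 and Hpd from 0.6157 to 0.7041. Cyp2b10 ran from 0.681 to 0.7354 and Cyp2d26 from 0.4318 to 0.4612. Vnn1 and Ugt2b37 lost their calls without male 1 (0.0539 each), Acot1 without female 1 (0.065) or female 2 (0.0625), and Gsta4 without male 1 (0.124), male 2 (0.137) or female 1 (0.0564). Haao also lost its call without the single array of male 1 at day 14 (0.0535), after centring (0.0535) and after a second quantile normalization (0.051).

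Interferon-stimulated genes, which answer viral RNA and interferon, fell as a list in day 7 against day 1: 10 of 27 fell and 0 rose, 15 adjusted over the list alone (median -0.41, adjusted p = 1.74e-09, adjusted p = 0.175 with an estimated correlation). Isg15 stood at -1.35 ± 0.19, Irf7 at -1.30 ± 0.16 and Rtp4 at -1.23 ± 0.185. Of 29 genes of the unfolded protein and integrated stress response 3 fell (11 adjusted over the list alone, adjusted p = 8.7e-07, adjusted p = 0.193 with an estimated correlation), including the chaperone genes Sdf2l1 (-0.64) and Creld2 (-0.56). The hypoxia and glycolysis list had 2 of 28 lower (4 adjusted over the list alone, adjusted p = 0.000603, adjusted p = 0.276 with an estimated correlation), with Adm, a vasodilator peptide gene, at -1.08. In the immediate early and heat shock list 3 of 30 fell (4 adjusted over the list alone, adjusted p = 0.0208, adjusted p = 0.276 with an estimated correlation), a call lost without male preparation 1 (0.124). Averaged over the sexes, all 31 cell cycle genes had values below 0 (median -0.21, adjusted p = 1.6e-05, adjusted p = 0.276 with an estimated correlation), while 1, Rrm2 of nucleotide synthesis, passed alone at -0.45 (2 adjusted over the list alone). The list medians were -0.54 and -0.37 in male preparations 1 and 2 and 0.05 and 0.04 in female preparations 1 and 2, so those of the females were not below 0. Rtp4, Creld2 and Rrm2 did not pass whichever preparation was left out, though their changes stayed close. Rtp4 ran from -1.353 to -1.102, Creld2 from -0.6145 to -0.5078 and Rrm2 from -0.4686 to -0.4218. Calls were lost for Irf7 without male 1 (0.085) or male 2 (0.0892), Isg15 without male 1 (0.0821), male 2 (0.119) or female 1 (0.0758), and Sdf2l1 without male 1 (0.186), male 2 (0.143) or female 1 (0.0891). Adm lost its call without male 1 (0.0663), female 1 (0.137) or female 2 (0.144).

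Extracellular matrix genes went both ways in day 7 against day 1: 8 of 32 fell and 3 rose (11 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.0131, adjusted p = 0.388 with an estimated correlation), and Col1a2, a fibrillar collagen gene, fell by 1.59 ± 0.27. Markers of stellate cells and fibroblasts, the matrix-producing cells of liver, moved with them: 0 of 17 passed over all genes and 4 fell adjusted over the list alone (median -0.52, adjusted p = 0.00504, adjusted p = 0.473 with an estimated correlation). Lrat, which stores vitamin A in stellate cells, had a value of -1.64 ± 0.40 (adjusted p = 0.0592). The stellate call was lost without male preparation 1 (adjusted p = 0.243), and the matrix call without male preparation 1 (0.0504) or female preparation 1 (0.0898). Endothelial markers had a median of -0.19 (adjusted p = 0.169), with Cdh5 of endothelial junctions at -1.25 ± 0.31 (adjusted p = 0.0597 without a block and 0.0208 with the preparation as a block). Chemokines and NF-kappa-B targets rose in 6 of 22 members (7 adjusted over the list alone, adjusted p = 0.00752, adjusted p = 0.388 with an estimated correlation), including Ccl20 by 0.90 and Tnfaip3, a brake on NF-kappa-B, by 0.72. Beside them, Kupffer cell and macrophage markers, genes of the liver's resident macrophages, had a median of 0.83 with 0 of 20 past the test alone and 0 adjusted over the list alone (adjusted p = 0.00616, adjusted p = 0.66 with an estimated correlation). Lyz2 (lysozyme) stood 2.45 ± 0.72 higher (adjusted p = 0.102 without a block and 0.00698 with the preparation as a block). Of 13 cholangiocyte and progenitor markers 4 rose and 1, Igf2, fell (6 and 2 adjusted over the list alone, adjusted p = 0.00752, adjusted p = 0.193 with an estimated correlation). Of 24 NRF2 targets, genes of antioxidant defence, 4 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.0367, and 0.0511 with the preparation as a block, adjusted p = 0.388 with an estimated correlation). The NRF2 call was lost without male preparation 1 (0.0515), male 2 (0.159) or female 1 (0.273). Of 18 p53 targets 1 rose (6 adjusted over the list alone, adjusted p = 0.000945, adjusted p = 0.193 with an estimated correlation), the apoptosis gene Pmaip1 by 0.81. Col1a2 lost its call without female 1 (0.153) or female 2 (0.145), and Ccl20 (0.055 to 0.22), Tnfaip3 (0.0672 to 0.212) and Pmaip1 (0.0665 to 0.238) lost theirs whichever preparation was left out.

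Core hepatocyte genes did not pass between days 7 and 1. Alb differed by 0.03, Hnf4a by -0.07, Cyp1a2 by -0.02, Cyp2e1 by 0.03 and Cyp3a11 by 0.53. Slc10a1, the bile acid importer, differed by 0.48, Abcb11, the bile salt export pump, by 0.23, Abcc2 by 0.13 and Cps1 of the urea cycle by 0.07, with adjusted p between 0.319 and 0.986. Cyp2e1 stood at -0.8748 in males alone, so its value averages changes of opposite sign in the sexes. By limma, 325 of 11861 genes were higher and 235 lower at day 7, 49 and 54 of them by at least 2-fold, and 2315 had an unadjusted p under 0.05 where chance gives 593.1. Of the 35 lists 13 stood higher and 7 lower with camera, 0 with an estimated correlation and 16 with fry. The count of 560 genes was 40, 75, 70 and 73 without male preparation 1, male 2, female 1 and female 2, and 956 with a trended and robust spread. Of 42 named genes that passed, 10, 14, 11 and 14 still did so when those preparations were left out, and Cldn6, Ptgs2, A2m and Lox passed in each case.

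Day 14 against day 1 covered the whole culture. The largest falls were those of 4 major urinary protein genes, which encode pheromone carriers secreted by liver: Mup9 stood at 11.64 ± 0.15 at day 1, 10.04 ± 0.79 at day 7 and 6.19 ± 1.39 at day 14 (SD, n = 4). Mup9 changed by -5.45 ± 0.265, Mup19 by -5.34 ± 0.30, Mup22 by -4.52 ± 0.235 and Mup2 by -4.45 ± 0.25 (adjusted p = 7.4e-05 each), with the same sign under both other scalings. Their identity is uncertain, since the copies are nearly identical and may read one another. The next falls were Ivl (-4.42 ± 0.64), Gvin1 (-3.53 ± 0.28), Csn3 (-3.35 ± 0.44) and Klrb1b (-3.04 ± 0.35). The largest rises were Dpysl3, a gene of cytoskeletal remodelling, from 5.61 ± 0.70 to 9.02 ± 0.53, and Cldn6 by 3.35 ± 0.27. Ptgs2 rose by 3.01 ± 0.18, Timp4, an inhibitor of metalloproteases, by 2.87 ± 0.18 and Cldn7 by 2.81 ± 0.28. Ptpn14 (2.67 ± 0.14), Anxa13 (2.59 ± 0.28) and Krt23 (2.54 ± 0.23) followed. Adjusted p for the 8 rises ran from 7.4e-05 to 0.000964, and all but Dpysl3 had a day 1 mean under 4.79. The 4 Mup genes, the 8 rises, Gvin1 and Klrb1b passed with any 1 preparation left out, while Ivl (0.0749) and Csn3 (0.065) lost their calls without male 1.

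**Figure D2:**
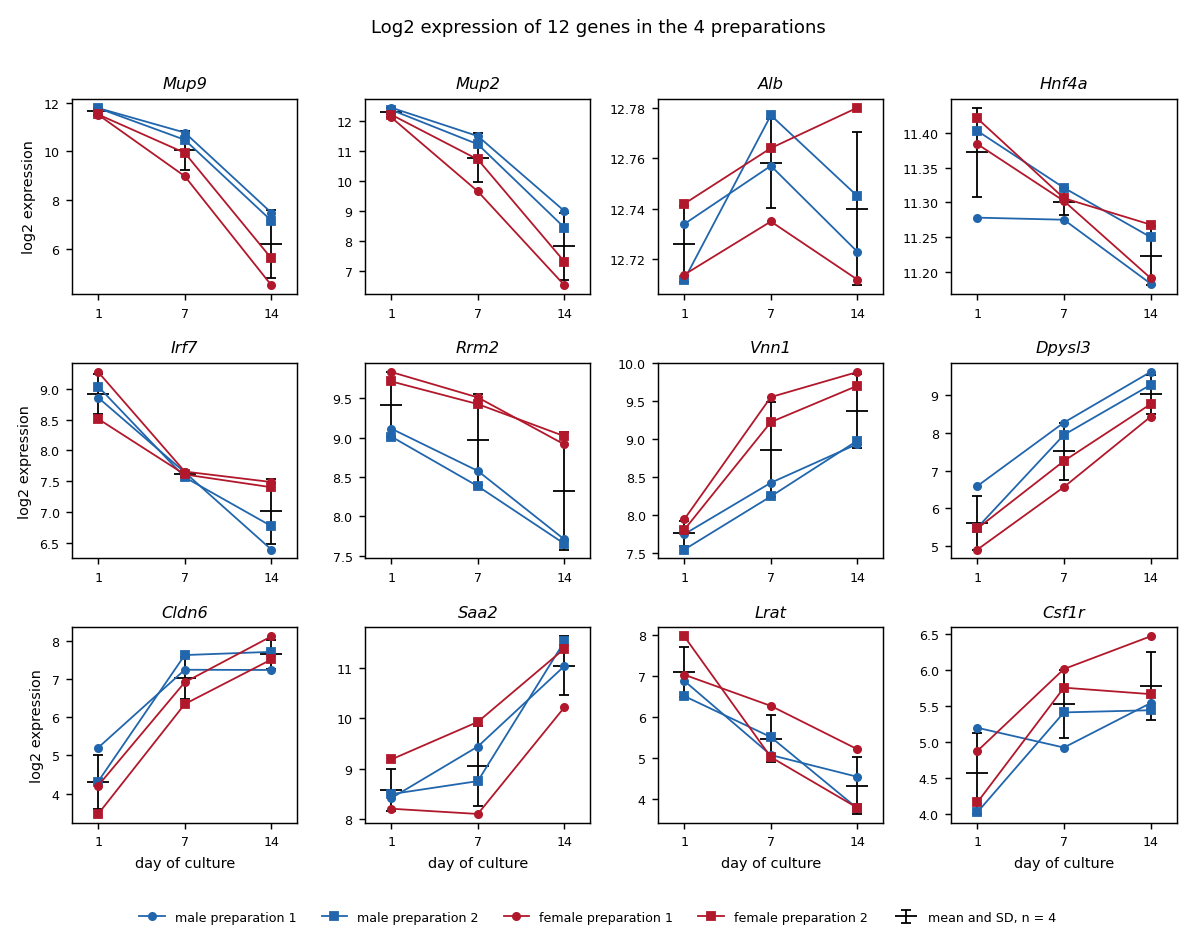
Log2 levels (y axis, a scale of its own in each panel) at days 1, 7 and 14 (x axis) of 12 genes, with a line per preparation and the mean with SD (n = 4) over it. Mup9 falls from 11.64 to 6.19 and Irf7 from 8.92 to 7.01, Saa2 rises from 8.58 to 11.04, and Alb stays near 12.73.

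Of the core hepatocyte genes none passed by limma between days 14 and 1, whether with or without the preparation as a block. Alb differed by 0.01 ± 0.05 (-0.02 after a second quantile normalization), Hnf4a by -0.15 ± 0.06, Cps1 by -0.12 ± 0.06, Cyp1a2 by 0.08 ± 0.15, Abcb11 by 0.38 ± 0.12 and Abcc2 by 0.22 ± 0.07, with adjusted p of 0.89, 0.12, 0.208, 0.791, 0.0722 and 0.0845. Slc10a1 (adjusted p = 0.995), Cyp3a11 (-0.66 ± 0.37, adjusted p = 0.293) and Cyp2e1 (-1.16 ± 0.67, adjusted p = 0.301) varied more between preparations. Among 45 plasma protein genes 3 rose and 8 fell (5 and 8 adjusted over the list alone, adjusted p = 0.739), and the median of 0.01 and mean of -0.02 had opposite signs. Complement gene C9 rose by 1.65, while the growth factor gene Igf1 fell by 1.46 and the clotting factor gene F11 fell by 1.37. Of 30 P450 genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.712, median -0.02 and mean -0.08, against an upward test). Cyp3a41a fell by 2.301 ± 0.44 and Cyp2c69 fell by 0.75 ± 0.18, though Cyp2c69 fell in 2 of 4 preparations and stood at 0.29 in males alone. Without male 1 and male 2 calls were lost for C9 (0.0866, 0.0937), F11 (0.0908, 0.0662) and Cyp3a41a (0.131, 0.0929). Cyp2c69 lost its call without male 1 (0.0663), female 1 (0.154), female 2 (0.116) or the single array of male 1 at day 14 (0.0727). The lists of efflux transporters (2 of 16 higher and 3 lower, 5 and 5 adjusted over the list alone, adjusted p = 0.739, median 0.01 and mean -0.03) and uptake transporters (2 and 4 of 12, 3 and 4 adjusted over the list alone, adjusted p = 0.615) did not pass. The drug efflux gene Abcb1a fell by 1.19. Oat, a pericentral gene of ornithine metabolism, fell by 1.13. Gluconeogenesis and glycogen genes had 2 of 17 lower (0 adjusted over the list alone, median -0.17, adjusted p = 0.051 without a block and 0.0464 with the preparation as a block, adjusted p = 0.639 with an estimated correlation and no block).

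Fatty acid oxidation and PPAR alpha targets rose in 23 of 36 members and fell in 1 in day 14 against day 1 (26 and 1 adjusted over the list alone, median 0.38, adjusted p = 2.37e-13, adjusted p = 0.142 with an estimated correlation). Acot1 rose by 1.74 ± 0.11, Vnn1 by 1.62 ± 0.10 and Cidec, a lipid droplet gene, by 1.54 ± 0.19. Of 30 acute phase genes, which liver secretes in inflammation, 11 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.00204, adjusted p = 0.586 with an estimated correlation). The serum amyloid genes Saa2, Saa1 and Saa3 rose by 2.47 ± 0.43, 1.93 ± 0.32 and 1.66 ± 0.30, and all 3 calls were lost without male 1 (0.0942, 0.0871, 0.0925) or male 2 (0.105, 0.0803, 0.126). Chemokines and NF-kappa-B targets rose in 7 of 22 and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.000764, adjusted p = 0.263 with an estimated correlation). Kupffer cell and macrophage markers stood higher beside these lists (median 0.94, 1 of 20 passed, 0 adjusted over the list alone, adjusted p = 0.0189, adjusted p = 0.67 with an estimated correlation), and Csf1r, the macrophage growth factor receptor, rose by 1.21 ± 0.29. The Csf1r call was lost without male preparation 1 (adjusted p = 0.0605), male 2 (0.149), female 1 (0.101), female 2 (0.0994) or the single array of male 1 at day 14 (0.0768). The Kupffer call was lost without male preparation 1 (adjusted p = 0.0813), male 2 (0.051) or the single array of male 1 at day 14 (0.0978). NRF2 targets rose in 10 of 24 and fell in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.000123, adjusted p = 0.142 with an estimated correlation), with the reductase gene Cbr3 at 1.18 and the efflux gene Abcc4 at 1.10. Of 18 p53 targets 6 rose (7 adjusted over the list alone, adjusted p = 0.000399, adjusted p = 0.142 with an estimated correlation), with Pmaip1 at 1.28 and the receptor gene Eda2r at 0.87. Conjugating enzymes rose in 10 of 36 and fell in 7 (17 and 7 adjusted over the list alone, adjusted p = 0.00812, adjusted p = 0.639 with an estimated correlation), and the sulfotransferase genes Sult2a8 and Sult1e1 had -1.92 and -1.07. The list call was lost without male preparation 2 (0.0759) or female 1 (0.0763). Sult2a8 lost its call without male 1 (0.0793), male 2 (0.102) or female 2 (0.0686), Sult1e1 without female 2 (0.106), and Eda2r without male 1 (0.0578) or male 2 (0.124). The respiratory chain list, 2 of 34 higher (0 adjusted over the list alone), had an adjusted p of 0.0228 (adjusted p = 0.142 with an estimated correlation), lost without male 1 (0.0826) or female 1 (0.105).

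YAP and TEAD targets, genes of a pathway that senses tension and cell contact, rose in 8 of 19 and fell in 1 in day 14 against day 1 (9 and 3 adjusted over the list alone, adjusted p = 0.00717, adjusted p = 0.251 with an estimated correlation). Tgfb2, a growth factor gene, rose by 1.86 and the receptor kinase gene Axl by 1.42, a call lost without male 2 (0.0527). Of 13 cholangiocyte and progenitor markers 6 rose and 2 fell (7 and 3 adjusted over the list alone, adjusted p = 0.00717, adjusted p = 0.142 with an estimated correlation), the fallers including Igf2 at -2.49 ± 0.24. The Igf2 value averages a larger fall in females and a smaller one in males, with the levels given under other observations. Of 40 cytoskeleton genes 9 rose and 2 fell (11 and 3 adjusted over the list alone), with camera at an adjusted p of 0.256 and fry at 0.00313. The actin-binding gene Tmsb4x rose by 1.23 and the tubulin gene Tubb2b by 1.61.

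Cell cycle genes fell in 19 of 31 members and rose in 0 in day 14 against day 1 (29 adjusted over the list alone, median -0.56, adjusted p = 2.79e-14, adjusted p = 0.142 with an estimated correlation). Rrm2 fell by 1.10 ± 0.07 and the cyclin gene Ccna2 fell by 0.95 ± 0.13. Beside them, stellate cell and fibroblast markers fell in 9 of 17 (12 adjusted over the list alone, median -1.30, adjusted p = 5.59e-07, adjusted p = 0.199 with an estimated correlation), with Lrat at -2.79 ± 0.40, the matrix gene Postn at -2.42 ± 0.415 and the receptor gene Pdgfrb at -1.90 ± 0.44. Endothelial markers fell in 5 of 16 (11 down and 2 up adjusted over the list alone, median -0.91, adjusted p = 0.000518, adjusted p = 0.421 with an estimated correlation), with Cdh5 at -2.404 ± 0.31 and the receptor gene Eng at -1.86 ± 0.32. Extracellular matrix genes went both ways, 8 of 32 higher and 10 lower (11 and 13 adjusted over the list alone, adjusted p = 0.511, median 0.05 and mean -0.29), and the collagen genes Col3a1 and Col1a2 had -2.99 and -1.99. Interferon-stimulated genes fell in 14 of 27 (18 adjusted over the list alone, adjusted p = 2.01e-09, adjusted p = 0.142 with an estimated correlation), with Irf7 at -1.91 ± 0.16, Oasl2 at -1.61 and Isg15 at -1.49. Of 28 hypoxia and glycolysis genes 10 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 7.51e-07, adjusted p = 0.142 with an estimated correlation), with Ankrd37 and Adm both at -1.52. Stress response genes fell in 12 of 29 and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 1.39e-06, adjusted p = 0.173 with an estimated correlation), with the glutathione-degrading gene Chac1 at -0.99 and the lipoprotein receptor gene Vldlr at -0.95. Cholesterol synthesis genes fell in 3 of 20 (4 adjusted over the list alone, adjusted p = 0.00714, adjusted p = 0.639 with an estimated correlation), including Idi1 (-0.40) and Msmo1 (-0.33), and that call was lost without male preparation 1 (0.219) or its day 14 array (0.0783). Without male 1, male 2, female 1 and female 2, Idi1 had adjusted p of 0.233, 0.0567, 0.162 and 0.158 and Msmo1 of 0.138, 0.105, 0.0573 and 0.121, and without the single array Idi1 had 0.0728. Without male 1 and male 2 calls were lost for Lrat (0.0569, 0.0604), Postn (0.0901, 0.0952), Oasl2 (0.113, 0.0815) and Vldlr (0.0523, 0.059). Without female 1 and female 2 they were lost for Pdgfrb (0.125, 0.188) and Eng (0.0753, 0.0924). Col1a2 lost its call without female 1 (0.0515), Ankrd37 without male 1 (0.0974), and Chac1 without male 2 (0.0963), female 1 (0.0975) or female 2 (0.0651).

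By limma, 900 genes were higher and 806 lower at day 14 than at day 1, 155 and 164 of them by at least 2-fold, and 3398 had an unadjusted p under 0.05. With camera 10 lists stood higher and 7 lower, with an estimated correlation 0, and with fry 18. The count of 1706 genes was 494, 583, 826 and 791 without male preparation 1, male 2, female 1 and female 2. Of 64 named genes that passed, 40, 44, 55 and 53 did so in those fits, all with the same sign.

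**Figure D3:**
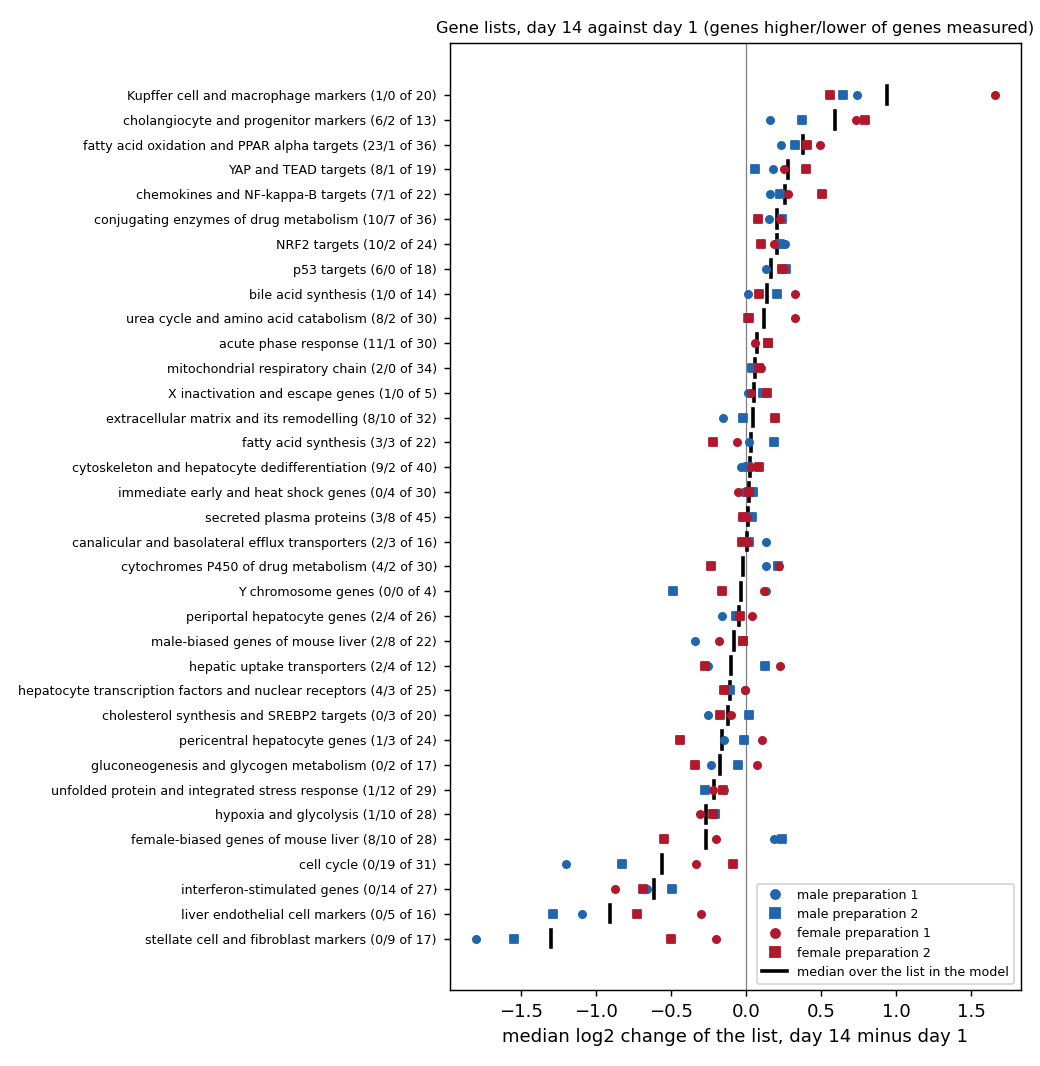
Median log2 change from day 1 to day 14 (x axis) of the measured members of 35 gene lists (y axis), with a point per preparation and a black bar for the median in the model. The stellate list lies lowest (model median -1.30) and the Kupffer cell list highest (0.94).

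Day 14 against day 7 asked what went on changing in the second week. The Mup genes fell further, with Mup19 at -4.02 ± 0.30, Mup9 at -3.85 ± 0.265, Mup22 at -3.11 ± 0.235 and Mup2 at -2.94 ± 0.25 (adjusted p = 0.00216 for the first 3 and 0.0037 for Mup2), with the same sign under both other scalings. Klrb1b (-2.17), Mt4 (-1.74), Lgi3 (-1.17) and the phosphate transporter gene Slc34a2 (-1.11) followed. The largest rises were Orm3, an acute phase glycoprotein gene (1.62 ± 0.24), Timp4 (1.49 ± 0.18), Slco3a1 (1.26 ± 0.21) and the protease inhibitor gene Spink1 (1.25 ± 0.19). Next came the cadherin gene Cdh6 (1.18 ± 0.11), Ptpn14 (1.14 ± 0.14), A2m (1.11 ± 0.18) and the chloride channel gene Ano1 (1.09 ± 0.17), with adjusted p from 0.00685 to 0.0461. Blocked by preparation, Slco3a1, A2m and Ano1 had adjusted p of 0.0716, 0.0538 and 0.0547, and after centring the arrays A2m had 0.0504. Core genes did not pass. Alb differed by -0.02, Hnf4a by -0.08, Cps1 by -0.19 and Cyp1a2 by 0.10. The others were Cyp2e1 by -1.19, Cyp3a11 by -1.19, Slc10a1 by -0.49, Abcb11 by 0.15 and Abcc2 by 0.09, with adjusted p from 0.184 to 0.917.

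Cell cycle genes were lower at day 14 than at day 7, with Rrm2 at -0.65 ± 0.07 and the kinase gene Aurkb at -0.42 ± 0.07 (2 of 31, 11 adjusted over the list alone, median -0.34, adjusted p = 7.59e-14, adjusted p = 0.268 with an estimated correlation). The list medians were -0.66, -0.41 and -0.34 in male 1, male 2 and female 1, while female 2 hardly changed (-0.02). Stellate markers (median -0.62, adjusted p = 9.13e-07, 0 of 17 passed, 0 adjusted over the list alone) and endothelial markers (median -0.61, adjusted p = 0.000117, 0 of 16 passed, 2 adjusted over the list alone) were lower too, each with adjusted p = 0.268 with an estimated correlation. Hgf, a growth factor gene of stellate cells, had -1.31 ± 0.52 (adjusted p = 0.313) and Lyve1 of endothelium -1.26 ± 0.42 (adjusted p = 0.229). All 20 cholesterol synthesis genes had values below 0 (median -0.21, adjusted p = 1.33e-09, adjusted p = 0.268 with an estimated correlation, 0 passed, 7 adjusted over the list alone), and Idi1 stood at -0.41 (adjusted p = 0.144). Gluconeogenesis and glycogen genes had a median of -0.23 (adjusted p = 1.13e-05, adjusted p = 0.268 with an estimated correlation, 0 of 17 passed, 6 adjusted over the list alone), with Ppp1r3c at -0.78 (adjusted p = 0.206). NRF2 targets (2 of 24 higher, 8 up and 1 down adjusted over the list alone), YAP and TEAD targets (2 of 19, 6 adjusted over the list alone) and cytoskeleton genes (3 of 40, 9 up and 1 down adjusted over the list alone) each had adjusted p = 0.000341 and adjusted p = 0.268 with an estimated correlation. Among their members Cbr3 rose by 0.68, Tgfb2 by 0.92 and Tubb2b by 0.75. Acute phase genes (3 of 30 higher, 12 up and 1 down adjusted over the list alone, adjusted p = 8.77e-05, adjusted p = 0.268 with an estimated correlation) included Cd14 at 0.53. Fatty acid oxidation genes (2 of 36, 7 up and 1 down adjusted over the list alone, adjusted p = 0.00108, adjusted p = 0.268 with an estimated correlation) included Acot1 at 0.71 and Acot2 at 0.52, a call lost without female preparation 1 (0.153). In the urea cycle and amino acid list Cth of cysteine synthesis fell by 0.48 (1 of 30, 9 down and 2 up adjusted over the list alone, adjusted p = 0.000634, adjusted p = 0.268 with an estimated correlation), a call lost without female 2 (0.0876). In the hypoxia list the mitophagy gene Bnip3 fell by 0.39 (1 of 28, 4 adjusted over the list alone, adjusted p = 0.000469, adjusted p = 0.268 with an estimated correlation). The cystine transporter gene Slc7a11, of the NRF2 and stress lists, rose by 0.62. In the fit with the preparation as a block Aurkb, Slc7a11, Cd14 and Acot1 had adjusted p of 0.0546, 0.0622, 0.0538 and 0.0546, and Cyp17a1, a female-biased steroid hydroxylase gene, 0.0155 against 0.0634 without (-1.40 ± 0.26). Kupffer markers did not pass (median -0.02 and mean 0.03, adjusted p = 0.872).

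Further lists passed in day 14 against day 7. Lower were plasma proteins (median -0.04, adjusted p = 0.00532), uptake transporters (-0.13, 0.045), fatty acid synthesis (-0.07, 0.00351), interferon-stimulated genes (-0.14, 0.0135), pericentral (-0.13, 0.0277), periportal (-0.08, 0.0135) and female-biased genes (-0.21, 0.00617). Of their members 0 passed over all genes. Adjusted over the list alone, 3 of 22 fatty acid synthesis and 5 of 26 periportal genes were lower, 4 of 28 female-biased genes were lower and 2 higher, and 2 of 45 plasma protein genes were lower and 1 higher. The counts were 0 for uptake, interferon and pericentral genes. Higher were chemokines (0.235, 0.00617), cholangiocyte markers (0.285, 0.0336), extracellular matrix (0.095, 0.0398) and immediate early and heat shock genes (0.05, 0.045). Of cholangiocyte markers 1 of 13 passed over all genes (5 up and 2 down adjusted over the list alone), and of the other 3 lists 0 did (4 of 22 chemokine genes up adjusted over the list alone, 0 in the others). With an estimated correlation none of these passed, at adjusted p of 0.427 for plasma proteins, 0.279 for fatty acid synthesis, 0.325 for the interferon and matrix lists and 0.268 for the rest. With the preparation as a block uptake transporters (0.0644), cholangiocyte markers (0.0617) and matrix genes (0.0644) were lost, while transcription factors (0.0485 against 0.0589), P450 genes (0.026 against 0.0541), bile acid synthesis (0.0299 against 0.0612) and p53 targets (0.0373 against 0.0527) passed. For these 4 lists adjusted p was 0.319, 0.513, 0.362 and 0.268 with an estimated correlation and no block. Calls were lost without male preparation 1 for plasma proteins (0.0593), uptake (0.17), interferon (0.272), matrix (0.548), immediate early (0.125), pericentral (0.0549) and periportal genes (0.125). Without male 2 those of cholangiocyte markers (0.188), matrix (0.127) and immediate early genes (0.0506) were lost, and without female 1 those of cholangiocyte markers (0.121), matrix (0.119) and immediate early genes (0.233). Without female 2 those of plasma proteins (0.0924), uptake (0.208), interferon (0.115), pericentral (0.325) and periportal genes (0.325) were lost. Without the single array of male 1 at day 14, plasma proteins (0.166), uptake (0.178), immediate early (0.131), pericentral (0.0897) and periportal genes (0.0761) were lost.

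By limma, 36 genes were higher and 22 lower at day 14 than at day 7. Of all genes, 1626 had an unadjusted p under 0.05. With the preparation as a block the count was 101, 51 higher and 50 lower, of which 46 were among the 58. It was 0, 2, 8 and 7 without male preparation 1, male 2, female 1 and female 2, and 9 without the single array of male preparation 1 at day 14. Of the 27 named genes that passed, 0, 0, 6, 7 and 7 did so in those fits. It was 146 with the dimmest genes left out and 309 with a trended and robust spread. The self-test called 94% of 2-fold changes at this number of arrays, a share that its simulated spreads may overstate. In the data 65 genes had an unadjusted p under 0.05 with at least a 2-fold change, and 18 of them passed. With camera 23 lists passed, with an estimated correlation 0 and with fry 5.

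Comparing both later days with the same day 1 arrays, 281 genes were higher and 200 lower at both days and 0 went opposite ways. Independent lists of those sizes would share 24.66 and 15.97. Unchanged groups simulated against shared day 1 arrays shared 0 genes (mean of 20 draws), with a correlation of changes across genes of 0.497 and a covariance of 0.0088, against 0.817 and 0.0866 in the data. With no effect simulated almost no gene passes, so the 0 was set beforehand and cannot be weighed against the shared counts. The simulation and the independent lists also left out what arrays of 1 preparation share. Deviations at days 7 and 14 correlated at 0.2237 in males and 0.3239 in females. The day 1 arrays were then split by preparation number, so that no day 1 array entered both differences. In this way 96 higher and 61 lower genes were shared in 1 split (7.34 and 2.81 for independent lists, correlation 0.643, covariance 0.0752) and 106 and 59 in the other (6.56 and 2.65, 0.679, 0.0785). Genes are not independent replicates, so no p is attached to these correlations.

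Male against female preparations over all days asked which genes differ by the sex of the donors (male minus female, 2 preparations each). The Y chromosome genes Eif2s3y (6.71 ± 0.10), Uty (6.52 ± 0.09) and Kdm5d (3.63 ± 0.22) were higher in the preparations labelled male. Reg3b, a secreted antimicrobial lectin gene, stood at 9.60 ± 0.38 in males and 5.09 ± 0.05 in females (SD, n = 2). Higher in males were also the scavenger receptor gene Scara5 (2.89 ± 0.21), the fatty acid hydroxylase gene Cyp4a12a (2.57 ± 0.185), A2m (2.56 ± 0.12) and the oxysterol hydroxylase gene Cyp7b1 (1.99 ± 0.12). Lower in males were the P450 gene Cyp2a4 (-2.89 ± 0.19), the peroxisomal transporter gene Abcd2 (-2.52 ± 0.15), the sulfotransferase gene Sult2a1 (-2.21 ± 0.16) and St3gal6 (-1.96 ± 0.07). So were Slc34a2 (-1.50 ± 0.09), the lipid transporter gene Mfsd2a (-1.37 ± 0.07), the vitamin E carrier gene Afm (-1.06 ± 0.07) and the mitotic checkpoint gene Bub1 (-1.004 ± 0.07). Adjusted p ran from 0.000314 (Eif2s3y, Uty) to 0.0423, and those other than Eif2s3y, Uty, Reg3b and St3gal6 lay between 0.0271 and 0.0423. Cyp4a12a had 0.0512 after a second quantile normalization. Cyp2a4, Sult2a1 and Cyp4a12a have close paralogs and are uncertain.

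**Figure D4:**
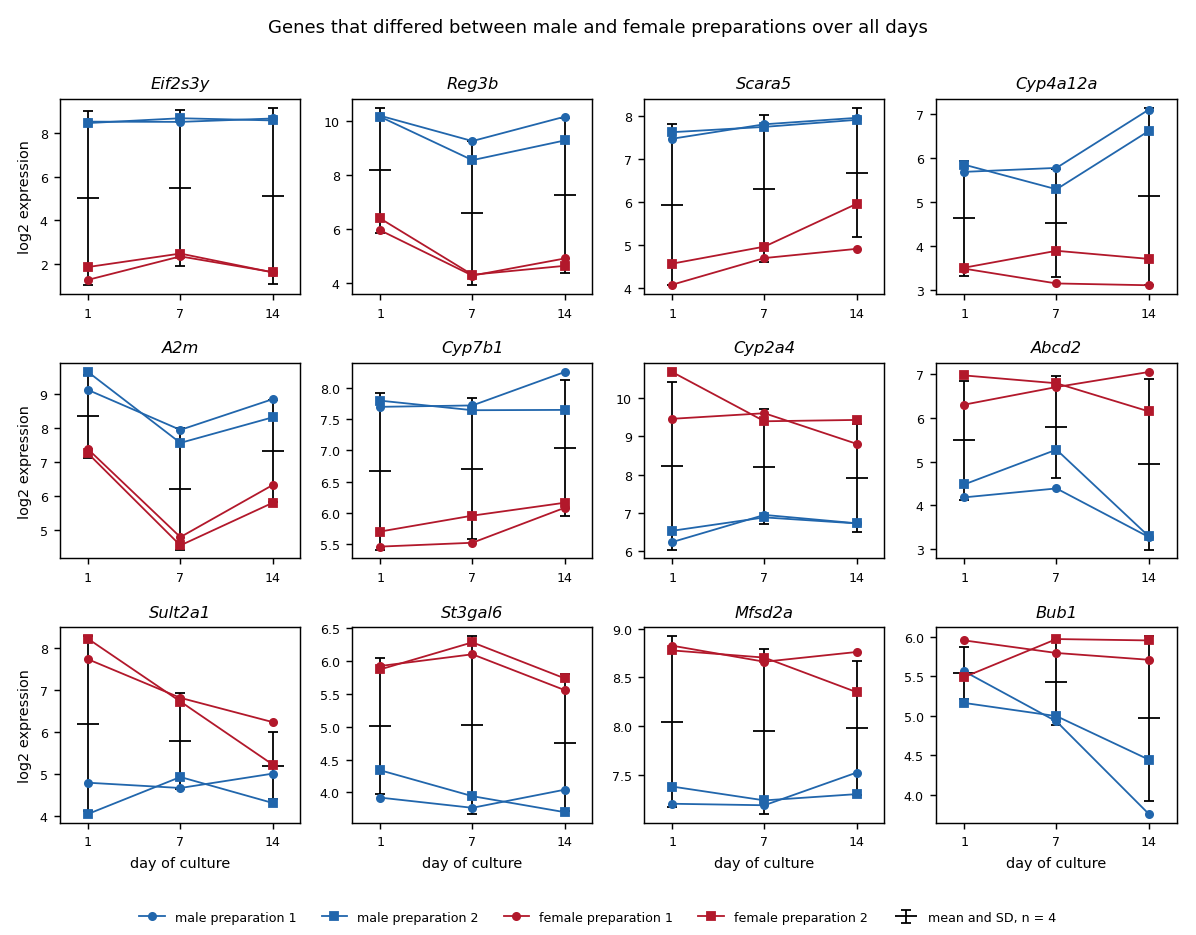
Log2 levels (y axis, a scale of its own in each panel) at days 1, 7 and 14 (x axis) of 12 genes, with points and lines for each male and female preparation and the mean with SD (n = 4) over both sexes at each day. Reg3b averages 9.60 in males and 5.09 in females, and Cyp2a4 6.67 and 9.57.

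The list of female-biased liver genes, fixed beforehand, was lower in male against female over all days: 3 of 28 passed (22 down and 1 up adjusted over the list alone, median -1.17, adjusted p = 4.91e-17, adjusted p = 0.287 with an estimated correlation). Of 22 male-biased genes 2 were higher (8 up and 3 down adjusted over the list alone, median 0.06, adjusted p = 0.0371, adjusted p = 0.515 with an estimated correlation), a call lost without male preparation 2 (0.257). P450 genes, which share members with the female-biased list, were lower (1 of 30, 19 adjusted over the list alone, median -0.86, adjusted p = 6.79e-13, adjusted p = 0.287 with an estimated correlation). So were cell cycle genes (2 of 31, 26 adjusted over the list alone, median -0.50, adjusted p = 1.59e-18, adjusted p = 0.287 with an estimated correlation). Lower too were pericentral genes (0 of 24, 12 adjusted over the list alone, median -0.59, adjusted p = 8.31e-08) and gluconeogenesis and glycogen genes (0 of 17, 11 adjusted over the list alone, median -0.39, adjusted p = 5.74e-09), both with adjusted p = 0.287 with an estimated correlation. Beside the cell cycle genes, stellate markers (median -0.52, adjusted p = 6.66e-07, adjusted p = 0.302 with an estimated correlation, 5 of 17 lower adjusted over the list alone) and endothelial markers (median -0.70, adjusted p = 0.000213, adjusted p = 0.464 with an estimated correlation) were also lower in males. Their members past the test over all genes numbered 0. Kdm6a, which escapes X inactivation, differed by -0.41 ± 0.08 (adjusted p = 0.105), and the X inactivation list had 0 of 5 past the test (4 lower adjusted over the list alone, adjusted p = 0.000247, adjusted p = 0.3 with an estimated correlation). Cytoskeleton genes (median 0.10, adjusted p = 0.00299, adjusted p = 0.287 with an estimated correlation) and YAP and TEAD targets (median 0.15, adjusted p = 0.00909, adjusted p = 0.302 with an estimated correlation) were higher in males, with 0 members past the test. Adjusted over the list alone, 4 cytoskeleton genes were higher and 1 lower, and 4 YAP and TEAD targets higher and 2 lower. Fatty acid synthesis (0 of 22, 8 adjusted over the list alone, adjusted p = 7.23e-09), urea cycle and amino acid genes (0 of 30, 10 adjusted over the list alone, adjusted p = 8.38e-07) and efflux transporters (0 of 16, 8 adjusted over the list alone, adjusted p = 0.000202) were lower in males, with adjusted p = 0.287 with an estimated correlation. Interferon-stimulated genes (median -0.07, adjusted p = 0.0371, adjusted p = 0.464 with an estimated correlation) and hypoxia genes (median -0.06, adjusted p = 0.00916, adjusted p = 0.515 with an estimated correlation) were lower. The interferon call was lost without male preparation 2 (0.175), female 2 (0.166) or the single array of male 1 at day 14 (0.604), and the hypoxia call without female 1 (0.158) or that array (0.0955). By limma, 11 genes were higher and 10 lower in males, and 2344 had an unadjusted p under 0.05. The count of 21 was 3 and 4 without male preparation 1 and male 2, and 26 and 20 without female 1 and female 2, and Eif2s3y, Uty and Reg3b passed in each case. The other genes named had adjusted p of 0.075 (Abcd2) to 0.226 without male 1, and, Abcd2 aside, of 0.0643 to 0.0889 without male 2. Abcd2, Afm, Bub1 and Sult2a1 also lost their calls without female 1 or female 2 (0.0621 to 0.0828), and Bub1 (0.119) and Slc34a2 (0.0969) without the single array of male 1 at day 14. It was 438 with the dimmest genes left out, 974 with a trended and robust spread, and 1210 with the preparation as a random effect over 12 arrays. With camera 25 lists passed, with an estimated correlation 0 and with fry 11.

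The sexes were also compared within each day, and the genes named here were chosen after their values were seen. At day 1 the female-biased genes Cyp3a41a (-4.78 ± 0.625, adjusted p = 0.0128), Cyp2b9 (-4.77 ± 0.52, adjusted p = 0.00569) and Sult2a2 (-4.68 ± 0.41, adjusted p = 0.00309), all uncertain because of paralogs, were lower in males. At day 7 Cyp2b9 (-4.39, adjusted p = 0.0154), Cdc6 of DNA replication (-1.20, adjusted p = 0.0154) and Rrm2 (-0.99, adjusted p = 0.00672) were lower. At day 14 Cyp2b9 (-4.10, adjusted p = 0.0134), Cyp3a11 (-3.79 ± 0.525, adjusted p = 0.0164) and Bub1 (-1.73, adjusted p = 0.017) were lower. The endothelial genes Plvap (-3.38 ± 0.50, adjusted p = 0.0195) and Eng (-2.82 ± 0.45, adjusted p = 0.0282) were lower too. Mup9 was higher (2.26 ± 0.375, adjusted p = 0.0309, higher under both other scalings). Without male preparation 1 none of the genes named at days 1 and 7 passed (Cyp3a41a 0.28, Cyp2b9 0.211 and Sult2a2 0.122 at day 1, Cyp2b9 0.33, Cdc6 0.293 and Rrm2 0.23 at day 7). Nor did any without male 2 (0.188, 0.135 and 0.122, then 0.155, 0.139 and 0.127). With only the arrays of the day compared, limma called 8, 4 and 4 genes at days 1, 7 and 14. The model over all 12 arrays takes the 3 arrays of a preparation as independent. By limma 91, 42 and 126 genes differed in it at days 1, 7 and 14 (41, 23 and 30 higher in males). At day 1 the count was 3, 9, 21 and 12, and at day 7 4, 18, 11 and 9, without male preparation 1, male 2, female 1 and female 2. At day 14 it was 14, 11 and 41 without male 1, female 1 and female 2 (113 without male 2), and 8 without the single array of male preparation 1, where none of the genes named passed (0.115 to 0.233). Of the genes named at day 14, Cyp2b9 (0.19), Cyp3a11 (0.129), Plvap (0.129), Mup9 (0.401) and Bub1 (0.164) lost their calls without male 1, and Cyp2b9 (0.0748) and Mup9 (0.161) without male 2. Without female 1 and female 2 those of Cyp3a11 (0.143, 0.119), Plvap (0.214, 0.116), Eng (0.25, 0.176) and Bub1 (0.139, 0.131) were lost, and that of Mup9 without female 1 (0.0724). Medians of the cell cycle list were -0.15, -0.58 and -0.91 at days 1, 7 and 14, with camera adjusted p of 0.022, 1.84e-20 and 1.33e-26 and adjusted p = 0.43, 0.0372 and 0.0508 with an estimated correlation.

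Whether the change over days differed between the sexes was tested directly. No gene passed by limma for the change from day 1 to day 7 (0 genes, 565 with an unadjusted p under 0.05 where chance gives 593.1) or to day 14 (0 genes, 815 with an unadjusted p under 0.05). With a trended and robust spread the counts were 0 and 14, and with the preparation as a block 0 and 1, the growth factor gene Igf2 at 3.47 ± 0.24 (adjusted p = 0.0387 with the block and 0.166 without). Without male preparation 2, 17 genes passed for day 14, all with a lower change in males. The self-test called 1.49% of 1.41-fold and 56.7% of 2-fold differences of this kind. Differences of 1.41-fold would thus mostly be missed here, and sizes between these 2 were not simulated. The simulated spreads may overstate both shares. For the change to day 14, 252 genes had an unadjusted p under 0.05 with at least a 2-fold difference. Of these 0 passed. Medians for the cell cycle list were -0.43 at day 7 and -0.77 at day 14 (camera adjusted p = 7.27e-13 and 5.78e-19, adjusted p = 0.234 and 0.178 with an estimated correlation). Beside them, stellate markers had -0.62 and -1.05 (camera adjusted p = 0.0721 and 5.42e-06, adjusted p = 0.88 and 0.506 with an estimated correlation). Endothelial markers had -0.30 and -0.80 (camera adjusted p = 0.612 and 0.000333, adjusted p = 0.994 and 0.598 with an estimated correlation).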

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

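The tests of the hepatocyte RNA share, of a single preparation and of probe copies for the Mup genes, of a general loss of other cells, and of cycling marker cells were chosen only after the result was seen. The tests of male preparation 1 alone for the marker lists and of a single preparation for the cell cycle list were written down first.

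The fall of Mup2, Mup9, Mup19 and Mup22 by day 14 had a median of -4.93. A smaller share of hepatocyte RNA would have lowered other secreted proteins as much, yet 20 plasma protein genes with a day 1 mean under 11, where the top of the scale hides no fall, had a median of 0.0981 (SD 0.647). The fall was not that of 1 preparation, since the medians were -3.8, -4.27, -6.25 and -5.4 in male 1, male 2, female 1 and female 2. The 4 changes lay within 0.999 of each other, and whether 1 transcript was read by several probe sets or each fell cannot be told apart without the probe sequences. A loss of Mup expression in culture stays open, and no biological explanation was tested.

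The 33 measured stellate and endothelial markers had a median change of -1.15 in day 14 against day 1, with 16 of 17 and 14 of 16 below 0. A general loss of cells other than hepatocytes would have lowered the markers of Kupffer cells too, which had a lowest preparation median of 0.557 (mean 0.899, SD 0.511). These markers cannot decide it, since their median day 1 level of 4.75 was near the background, and the list's call was lost without male 1 (0.0813), male 2 (0.051) and with an estimated correlation (adjusted p = 0.67). Without male preparation 1 the median of the markers was -0.752, so that preparation alone did not make the pattern. Male 2, kept in that fit, had medians of -1.545 (stellate) and -1.285 (endothelial), against -1.802 and -1.093 in male 1. The fall was smaller in females, at -0.2019 and -0.2995 in female 1 and -0.5005 and -0.7266 in female 2. A general loss of other cells therefore stays open, as do a loss of stellate and endothelial cells alone and lower expression in cells that stayed, which were not tested.

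Cell cycle genes fell further in male preparations by day 14, with a sex difference in the change of -0.773 (camera adjusted p = 5.78e-19, adjusted p = 0.178 with an estimated correlation, fry adjusted p = 0.0492). A single preparation did not make this, since the difference was -0.633, -0.82, -0.975 and -0.595 without male 1, male 2, female 1 and female 2. The stellate and endothelial markers also had a sex difference of -0.846, but within females the order was opposite: female 2 had the lower markers (-0.5005 and -0.7266 against -0.2019 and -0.2995 in female 1) and the smaller cell cycle change (-0.08509 against -0.3317). With 2 preparations per sex and whole spheroids, fewer cycling cells of those types and slower cycling of hepatocytes cannot be told apart. Sex of the animals as a biological difference stays open and untested, with 2 pools per sex.

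The following lists also passed a direct test of the sex difference in the change with camera. None passed with an estimated correlation (lowest adjusted p of those named 0.234 to day 7 and 0.302 to day 14). With fry 0 lists passed to day 7 (lowest adjusted p = 0.254). To day 14 fry called 1 list, the cell cycle list above (0.0492). From day 1 to day 7 the differences were 0.101 for P450 genes, -0.158 for fatty acid oxidation, 0.14 for cholesterol synthesis, 0.267 for fatty acid synthesis, -0.182 for extracellular matrix, -0.429 for the cell cycle and 0.507 for female-biased genes. Preparation medians of the sexes overlapped for P450 genes (males 0.239 and 0.170, females 0.195 and 0.167). They also did for fatty acid oxidation (0.285 and 0.256, 0.266 and 0.377) and matrix (-0.351 and -0.047, -0.216 and 0.010). In the other lists named here they did not overlap. From day 1 to day 14 the differences were -0.112 for the urea cycle and amino acids, -0.207 for fatty acid oxidation, 0.217 for fatty acid synthesis, -0.276 for chemokines, -0.348 for extracellular matrix, 0.575 for female-biased genes, -0.797 for endothelial and -1.05 for stellate markers. In the urea cycle list female 1 stood at 0.328, against 0.011, 0.016 and 0.021 in male 1, male 2 and female 2.

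In 19 of 273 sets of 4 preparations 1 preparation stood far from the others, where chance gives about 1 in 20 (13.6), and 10 of these were female 1, 4 male 1, 3 male 2 and 2 female 2. In the change from day 1 to day 7, female 1 stood apart for urea cycle genes (0.271, others 0.158 to 0.173), acute phase genes (-0.089, others 0.062 to 0.0791), Sdf2l1 (-1.17, others -0.501 to -0.406) and Abcc2 (0.243, others 0.0722 to 0.0979). Male 1 stood apart for stellate markers (-1.24, others -0.205 to -0.124), Adm (-1.95, others -0.82 to -0.764) and Col1a2 (-2.88, others -1.29 to -1.02). Male 2 did so for conjugating enzymes (0.228, others 0.117 to 0.122), Dpysl3 (2.46, others 1.66 to 1.79) and Alb (0.0646, others 0.0214 to 0.0229), and female 2 for Cyp1a2 (-0.338, others 0.0636 to 0.11). In the change from day 1 to day 14, female 1 stood apart for urea cycle (0.328, others 0.0111 to 0.021), acute phase (0.0588, others 0.145 to 0.15), hypoxia (-0.307, others -0.217 to -0.204) and Kupffer cell lists (1.66, others 0.557 to 0.738), female 2 for Anxa13 (2.28, others 2.67 to 2.72) and male 1 for Csf1r (0.341, others 1.41 to 1.59). From day 7 to day 14 female 1 stood apart for hepatocyte transcription factors (0.0241, others -0.0924 to -0.0739) and conjugating enzymes (0.142, others -0.0332 to -0.0149).

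Of 1192 probe sets with no gene symbol, which entered no comparison, 161 passed between days 14 and 1 when all probe sets were tested, 73 higher and 88 lower.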

How the results depend on the processing

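Leaving out the single array of male preparation 1 at day 14 was chosen only after the result was seen, and the other tests of settings were planned. Of 3665 values of 202 pairs of a named gene and a comparison, 2876 kept direction and side of the threshold, 743 lost the call, 26 gained it and 20 turned direction, 1 of them of a gene that had passed. Where a preparation is left out, the lone array left in a group is assumed to vary like the other groups. Precision is lower in those fits, so a lost call alone does not show that 1 preparation made the change. A trended and robust spread gave 956 genes for day 7 against day 1, 309 for day 14 against day 7, 974 for male against female over all days, 292, 178 and 411 for the sexes at days 1, 7 and 14, and 14 for the sex difference in the change to day 14. With the 40% dimmest genes left out, which also changes the spread limma borrows between genes, counts were 146 for day 14 against day 7, 438 for sex over all days and 176 and 94 for the sexes at days 1 and 7. An adjusted p under 0.05 with a 2-fold change gave 103, 319 and 18 genes for the day comparisons (days 7 and 1, 14 and 1, 14 and 7) and 60 and 82 for the sexes at days 1 and 14. An adjusted p under 0.01 gave 110, 679 and 6, 2 for sex over all days, and 30, 11 and 13 for the sexes within days. An unadjusted p under 0.05 with a 2-fold change gave 142 and 350 for days 7 and 14 against day 1, 128 for sex over all days, 147, 138 and 264 within days, and 80 and 252 for the sex difference in the changes to days 7 and 14. Using only the arrays of the days compared, which leaves fewer samples, gave 23 for day 14 against day 7 and 8, 4 and 4 for the sexes within days. Males alone gave 64, 795 and 2 genes and females alone 103, 567 and 5 for the day comparisons. Without the single array, day 14 against day 7 gave 9 and the sexes at day 14 gave 8.

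With the preparation as a block, day 14 against day 7 gave 101 genes and the sex difference in the change to day 14 gave 1. Among the named genes and the lists of the day comparisons it changed no other call than those printed in the report. Over all genes, 430 of the 560 calls for day 7 against day 1 and 1447 of the 1706 for day 14 against day 1 stayed. Male and female donor numbers name different preparations, and a block on them gave 26 genes over all days against 21, with Kdm5d, Cyp4a12a, Cyp7b1, Afm, Bub1 and Rrm2 past 0.05 at adjusted p from 0.0565 to 0.0604. Of the 21 genes only 11 were among the 26, of which 9 were higher and 17 lower in males. For sex over all days the preparation as a random effect gave 1210 genes and 12 independent arrays with day as a covariate 1216. The correlation estimated within a preparation was 0.00198, so both fits took the 12 arrays of 4 preparations as nearly independent. On the 4 preparation means a trended and robust spread gave 974 genes, with all 21 among them. The count thus also depends on how the spread is modelled. With 1 preparation left out, counts ran from 40 to 75 (day 7 against day 1), 494 to 826 (day 14 against day 1), 0 to 8 (day 14 against day 7), 3 to 26 (sex over all days), 3 to 21, 4 to 18 and 11 to 113 (the sexes at days 1, 7 and 14) and 0 to 17 (sex difference in the change to day 14). Of the 35 lists, an estimated correlation gave 0 in each of the day comparisons and 0 for sex over all days against 20, 17, 23 and 25, and fry gave 16, 18, 5 and 11.

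Values that turned direction were, in day 7 against day 1, Cyp1a2 at 0.0661 and Cyp2e1 at -0.8748 in males alone, Cyp2e1 at -0.01676 without male 1 and -0.2486 without female 1, and Cyp1a2 at 0.08785 without female 2. Leave-one-out values of Cyp1a2 began at -0.1359 and those of Cyp2e1 ended at 0.3146. In day 14 against day 1 they were Alb at -0.01993 and Slc10a1 at 0.01197 after a second quantile normalization, Cyp2c69 at 0.2921 in males alone, Cyp3a11 at 0.1029 and Slc10a1 at 0.113 in females alone, Cyp1a2 at -0.0284 and Slc10a1 at 0.2673 without the single array, Cyp1a2 at -0.08939 without male 1 and -0.09525 without female 1, and Slc10a1 at 0.153 without male 1 and 0.2305 without female 2. The other ends of the leave-one-out values were 0.2492 for Cyp1a2 and -0.2372 for Slc10a1. In day 14 against day 7 they were Cyp1a2 at -0.0319 in males alone, -0.004355 without the single array and -0.06409 without male 1, and Hgf at 0.1273 in females alone. Without male 2 Cyp1a2 had 0.2661. Except where fewer samples are named above, the cause was not tested. Signal over background may limit genes with a day mean under 4.79, and whether their changes are understated was not tested.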

Other observations

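The paragraphs on Igf2 and on further Mup genes, and the tests of other splits of the arrays, were chosen only after the result was seen.

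Igf2, a fetal growth factor gene that adult mouse liver keeps silent, differed between the sexes at the start of culture. At day 1 male preparations stood at 6.67 and 7.40 and female ones at 10.81 and 11.32 (male minus female -4.03 ± 0.34, limma adjusted p = 0.00299). By day 14 the levels were 6.30 and 6.27 in males and 6.51 and 7.19 in females (-0.56, adjusted p = 0.514). At day 7 the difference was -1.68 ± 0.34 (adjusted p = 0.0952). The day 1 call was lost without male preparation 1 (adjusted p = 0.122) or male 2 (0.0576).

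Other Mup genes moved less than the 4 with the largest falls. Mup20, known as darcin, rose from 11.63 ± 0.29 at day 1 to 12.10 ± 0.11 at day 14 (SD, n = 4, limma adjusted p = 0.00592), a call lost without male preparation 1 (0.0539) or male 2 (0.107). Mup3 changed by -0.73 (adjusted p = 0.00459), Mup5 by -1.40 (adjusted p = 0.00456), Mup6 by -0.47 (adjusted p = 0.041) and Mup21 by -0.58 (adjusted p = 0.0202), with the same signs under both other scalings. Calls were lost without male 1 for Mup3 (0.0927), Mup5 (0.102), Mup6 (0.234) and Mup21 (0.169), and without male 2 for Mup5 (0.0613) and Mup6 (0.235). Mup6 also lost its call without female 2 (0.0672) or the single array of male 1 at day 14 (0.0715), and Mup21 without female 1 (0.0971) or female 2 (0.124). All are uncertain because of near-identical copies.

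Other splits of the 8 arrays of a day comparison into 2 groups of 4, fitted with a term for sex, were counted. For day 7 against day 1 the real split gave 553 genes and the highest other 0, for day 14 against day 1 1330 and 0, and for day 14 against day 7 62 and 1. In each case 1 of 34 splits, the real one, gave as many. Most of these splits ignore that the 8 arrays are 4 preparations sampled on both days. Without the term for sex the real splits gave 133, 810 and 0 genes of 35 splits, and the split by sex gave 64, 19 and 154. Each side of the split by sex held 4 arrays from 2 pools, fitted as if independent, so its counts mix sex with pool. Only 8 splits, the real one included, part all 4 pairs, which is too few for a share under 0.05. The highest other of these gave 0 genes in each comparison without the term for sex, and the remaining splits put both arrays of some preparations in 1 group.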
